A study of Homo sapiens with 4 samples.

How the data were processed

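Circular RNAs (circRNAs, RNA loops closed by backsplicing of a downstream exon end onto an upstream exon start) were profiled in Flp-In T-REx 293 cells, a human embryonic kidney line with a defined integration site for inducible transgenes. Per the labels, every line carried an integrated, inducible copy of Flag-HA tagged DIS3, the ribonuclease that also serves as a catalytic subunit of the RNA exosome. In DIS3 KD clone 8 the endogenous gene had been disrupted with CRISPR/Cas9. The labels speak of knock down because some DIS3 remained without induction, and the column names mark all libraries as made without doxycycline. There were 2 control and 2 DIS3 KD libraries, described as biological replicates, made from rRNA-depleted total RNA with a strand-keeping kit.

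Per the submitters' processing notes, bcl2fastq 2.20, Bowtie2 2.3.5 and genome build hg38 were used, and the circRNA caller is not given in the sources used here. The deposited FPBcirc values are a depth-normalised signal, backsplice fragments per gigabase of mapped sequence, per the file headers and the values. The deposited CIRCscore is a ratio of FPBcirc to the linear signal of the host gene (FPBlinear). The deposited fold change between group means is a ratio as well, and it equalled the KD mean plus 0.1 over the control mean plus 0.1 for every circRNA. The deposited table listed 45182 circRNAs from 8230 host gene symbols, of which 8192 matched a current symbol, and 7 lines had been emptied before use. No genome sequence was used here, so positions are those of the deposited table on hg38, converted to a first base counted from 1, and exon content and strand of the circles are not given.

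Every nonzero FPBcirc value was a whole multiple of the smallest value in its library, within a tolerance of 0.001 of a read, for 100% of values. Reads and depth were recovered from that step. Control replicates 1 and 2 held 48895 and 55193 backsplice reads on 19.6 and 20.4 mapped gigabases, and DIS3 KD replicates 1 and 2 held 352471 and 121507 on 165 and 47.9. One read was worth 0.0511, 0.0489, 0.00604 and 0.0209 FPB in these libraries, so a circRNA below that level could not be seen. Over both control libraries together, 3 reads correspond to 0.0750 FPB, the limit that a count of 0 allows. Reads carry no molecular identifiers, so this limit covers counting error only.

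FPBlinear was derived from each CIRCscore as (FPBcirc + 0.01) / CIRCscore minus 0.01, the form that left no negative value. It exists only in libraries where the circRNA was detected. Within a library it was a single value per host gene for at least 99.8% of hosts with several circRNAs, so it was tested once per host gene for the 2547 hosts with a value in all 4 libraries, an analysis added after the values were seen, as well as once per circRNA as planned.

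Groups were compared with limma 3.58.1 in R 4.3.3 on log2(value + pseudocount), with a variance trend and robust moderation, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on the log2(value + pseudocount) scale, which understates the change of low circRNAs. The FPB pseudocount was 0.0349, the median over libraries of the value of 1 read, and 2427 circRNAs with a mean of at least 5 times that (0.174 FPB) were tested. CIRCscore was tested for the 1823 of them with a value in all 4 libraries, with a pseudocount of 0.00448, the percentile 5 of their values. Both groups hold 2 libraries, so an exact permutation test of a single value cannot give a p below 0.333. Host gene lists and circRNA classes were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. All 10 lists were fixed before the data were examined, as were the main tests, the rule for naming and the other settings tried unless said otherwise.

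The rule named, for FPBcirc and CIRCscore, the 12 circRNAs with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap. Directions with fewer than 12 were filled to 8 by the smallest unadjusted p, given as values that did not pass. It added every tested circRNA of DIS3, DIS3L and DIS3L2, the 10 most abundant circRNAs and the 4 with the smallest p in each list. The same rule was applied to linear host RNA after the values were seen.

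Alternatives were the replicate number as a block, leaving out each library, other pseudocounts, filters and scalings, limma without trend and robust moderation, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. Thinning the KD reads to control depth was added later. Figures were drawn with matplotlib 3.10.9. The values of 1 circRNA past the threshold are not reported here.

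The fits were tested on simulated data with 200 features changed by 4-fold or 16-fold. For FPBcirc, reads were drawn with a common spread for all circRNAs of a pair of libraries. With each pair of libraries given its own measured spread, the FPBcirc fit over 2427 circRNAs recovered 0% of the 4-fold and 1% of the 16-fold changes, with 0 false calls. With both pairs given the smaller spread of the KD pair, it recovered 48% and 100%, with 7 false calls. The CIRCscore fit over 1823 circRNAs recovered 38% of the 4-fold and 100% of the 16-fold changes. For FPBlinear over 2547 host genes the shares were 99% and 100%. CIRCscore and FPBlinear were simulated with normal noise on the log2 scale, of a common size per pair. Their shares do not compare directly with those of FPBcirc. Among the 809 most abundant simulated circRNAs, with each pair given its own spread, the FPBcirc fit recovered 0% of the 4-fold and 3.23% of the 16-fold changes. As the spread was common to all circRNAs of a pair, these shares do not describe circles of narrower spread. A 3.79-fold fall of a MAN1A2 circle was called in the data, but its true change is not known.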

Results

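Backspliced reads and their host genes were compared between DIS3 KD clone 8 and control cells, 2 libraries each, to find circRNAs whose level changed when DIS3 was depleted. DIS3 is a 3' to 5' exonuclease and endonuclease. Control libraries showed 8357 and 8566 circRNAs with at least 1 read, and the KD libraries 32259 and 20231. Depth differed in the same direction, from 19.6 and 20.4 mapped gigabases in the controls to 165 and 47.9 in the KD libraries. With reads thinned to the depth of control replicate 1, the KD libraries still showed 13659 and 13819 circRNAs against 8357 and 8472 in the controls (means of 20 draws). Of the 45182 circRNAs listed, 31465 were read in KD libraries alone, 4403 in control libraries alone and 2617 in all 4. Across the 2427 tested circRNAs, log2 FPBcirc correlated at r = 0.366 between the control libraries and at r = 0.818 between the KD libraries, across circRNAs, which are not independent replicates. Libraries of different groups correlated at r = 0.318 to 0.346. The controls were thus hardly closer to each other than to the KD libraries. Only 1 KD clone was profiled, so effects of the clone and of DIS3 depletion were not separable here.

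The targeted gene itself gave too few backsplice reads to check the labels. Its 2 circRNAs on chromosome 13 (72773684 to 72777493 and 72773684 to 72778380) together had 0 reads in both control libraries and 7 and 2 reads in KD replicates 1 and 2. The summed KD levels of 0.0423 and 0.0417 FPB lie under the 0.0750 FPB that 0 reads in the pooled controls allow. Linear DIS3 RNA could be derived for the KD libraries alone, at 11.7 and 15.9 FPB. The cytoplasmic paralogue DIS3L had 3, 0, 7 and 6 backsplice reads, and DIS3L2, the exonuclease that degrades uridylated RNA, had 15, 31, 188 and 45. The single DIS3L2 circRNA that passed the abundance filter (chromosome 2, 232014835 to 232030080) stood at 0.895 ± 0.326 FPB in controls and 0.449 ± 0.134 in KD (SD, n = 2 each; log2 fold change -0.92, SE 0.47, limma adjusted p = 0.309).

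Total circRNA signal per mapped base had a lower mean in KD. Summed FPBcirc was 2600 ± 141 in controls and 2333 ± 287 in KD (SD, n = 2 each), a ratio of 0.897 (exact permutation p = 0.667, two-sided; the smallest p this design allows is 0.333). Over the tested circRNAs alone the ratio was 0.774, with both KD libraries below both controls (1193 and 1481 against 1658 and 1796; exact permutation p = 0.333, two-sided). The filter uses the mean over all libraries, where the controls scatter more, so it can favour circRNAs high in a control. Those below the filter summed higher in both KD libraries than in both controls. Without CDR1-AS, the circle with the highest mean over the 4 libraries, the ratio over all circRNAs was 0.872, again with both KD libraries below both controls (exact permutation p = 0.333, two-sided).

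**Figure D1:**
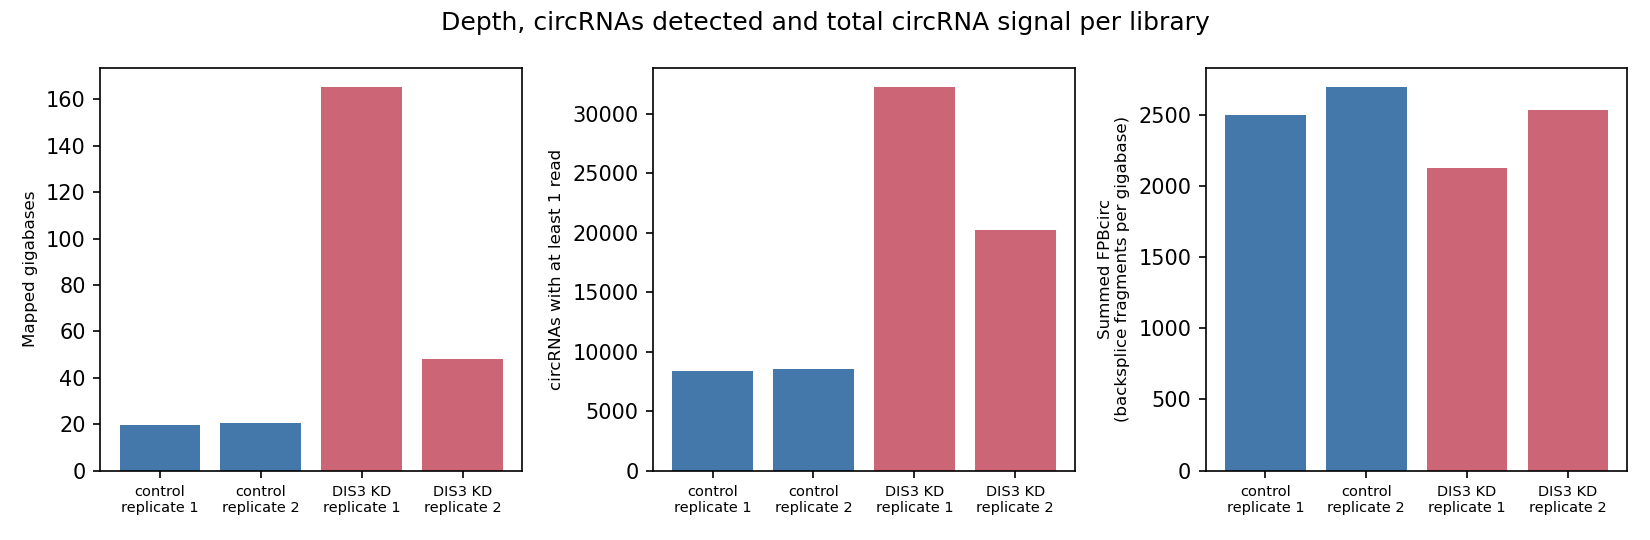
Mapped gigabases, number of circRNAs with at least 1 read, and summed FPBcirc for each of the 4 libraries (blue, control; red, DIS3 KD). Mapped gigabases range from 19.6 to 165 and circRNAs from 8357 to 32259, while summed FPBcirc ranges from 2130 to 2700.

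CDR1-AS, the circular antisense transcript known as a sponge for miR-7, was about 10.1-fold higher in KD cells, where it was the most abundant circRNA; in controls it ranked 15. It lies on chromosome X, 140783176 to 140784660, and rose from 6.99 ± 2.22 to 70.6 ± 9.99 FPB (SD, n = 2 each), with 106 and 175 reads in the controls against 10506 and 3719 in KD (log2 fold change 3.36, SE 0.27, limma adjusted p = 0.00882). No linear reads were listed for it. A circRNA of TBCD, a tubulin folding cofactor, lies on chromosome 17, 82903405 to 82911789. It had 0 reads in both control libraries and 250 and 99 (1.51 and 2.07 FPB) in KD (limma adjusted p = 0.0444). The mean KD level was 23.8-fold the limit set by 3 reads over the pooled controls. That limit covers counting error only, and at equal depth 45.9% of circRNAs with 5 or more reads in 1 control had 0 in the other. Another TBCD circle (82805875 to 82814934) had 7 and 9 control reads and 39 and 5 in KD (log2 fold change -1.15, limma adjusted p = 0.368). Linear TBCD RNA was higher in KD (log2 fold change 0.69, limma adjusted p = 0.0325). CDR1-AS and the first TBCD circle were the only 2 circRNAs that rose past the threshold, while 11 fell. CDR1-AS was also the single circRNA called by edgeR on the recovered reads (adjusted p = 0.0205).

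The circRNAs that fell came from 10 host genes. MAN1A2, a mannosidase of N-glycan trimming, gave 2 circles that share a start on chromosome 1 at 117402186. The circle ending at 117442325 went from 13.5 ± 1.63 to 2.66 ± 0.722 FPB, and that ending at 117414831 from 12.9 ± 0.374 to 3.40 ± 0.562 (SD, n = 2 each; log2 fold changes -2.35 and -1.92, SE 0.29 and 0.26, limma adjusted p = 0.0444 for both). Circles of NR3C1, the glucocorticoid receptor (chromosome 5, 143399656 to 143400852; log2 fold change -2.61), and of MCM3, a subunit of the replicative helicase (chromosome 6, 52267865 to 52269226; -3.20), fell as well. So did those of IGF2R, the mannose 6-phosphate receptor (chromosome 6, 160046498 to 160048543; -3.29), and PTGES3, the HSP90 co-chaperone p23 (chromosome 12, 56666204 to 56670364; -3.50). Further circles were from SDF4 (chromosome 1, 1223244 to 1223968; -3.16), VAPB (chromosome 20, 58438945 to 58441083; -2.54), ZDBF2 (chromosome 2, 206279540 to 206297373; -2.51) and ANKRD13C (chromosome 1, 70292388 to 70315566; -2.33). Their limma adjusted p lay between 0.0444 and 0.0486.

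**Figure D2:**
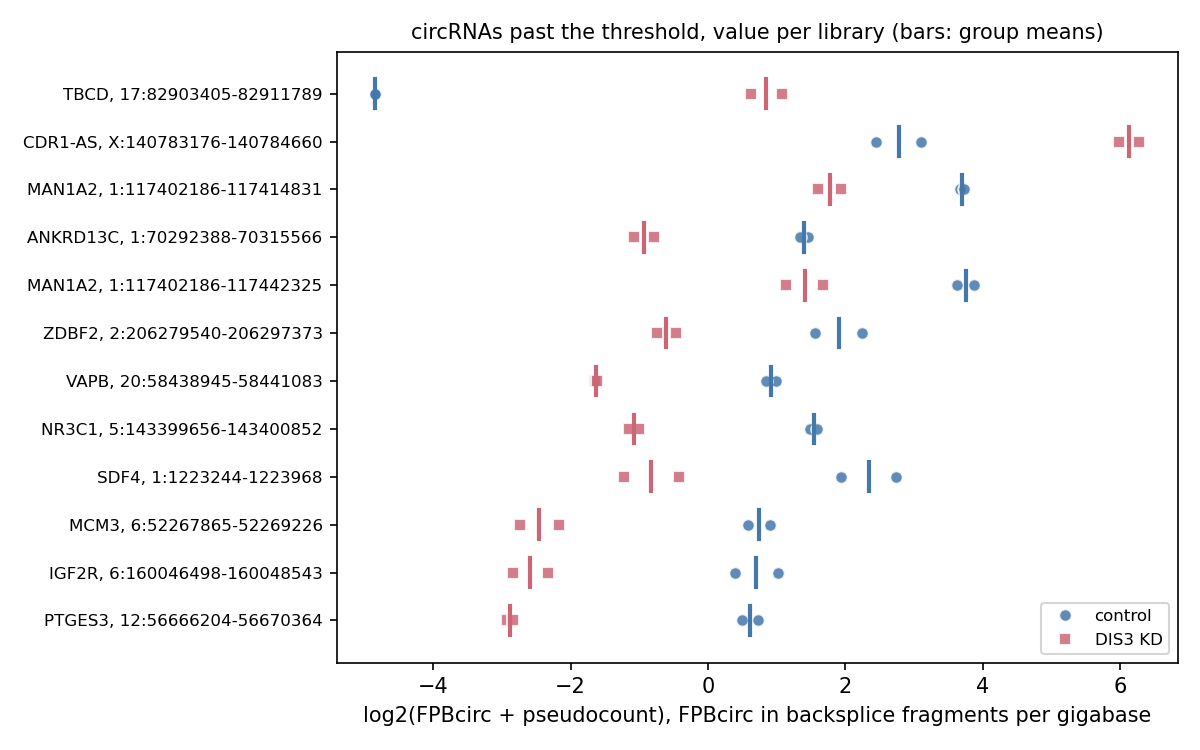
log2(FPBcirc + pseudocount) in each library for 12 of the 13 circRNAs past the threshold (circles, control; squares, DIS3 KD; vertical bars, group means of 2 libraries). CDR1-AS (log2 fold change 3.36) and TBCD (5.69) lie higher in both KD libraries, and the other 10 shown lie lower in both.

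Further named circles, higher or lower in KD, did not pass the threshold. Some came close to it, and others were named for their abundance. AKT2, a serine/threonine kinase of insulin signalling, had a circle on chromosome 19 (40255158 to 40265351) at 0.496 ± 0.267 FPB in controls and 3.36 ± 0.142 in KD (SD, n = 2 each; limma adjusted p = 0.0533). A circle of FARSA, a subunit of phenylalanyl-tRNA synthetase (chromosome 19, 12928342 to 12928847), stood at 0.428 ± 0.190 and 2.67 ± 0.393 FPB (limma adjusted p = 0.0577). For RBM33 the reads were 0 and 1 in controls and 183 and 65 in KD, for MYBL2 0 and 2 against 248 and 66, and for PLPBP 0 and 0 against 151 and 77. Among the most abundant circles, CAMSAP1 had 15.1 ± 0.545 and 31.1 ± 0.20 FPB (adjusted p = 0.0647) and GCN1 10.2 ± 0.177 and 13.7 ± 1.82 (adjusted p = 0.322), from limma with n = 2 each. Lower KD values that did not pass were found for another MAN1A2 circle with the same start, ending at 117420649 (27.5 ± 7.27 and 7.93 ± 1.92 FPB, adjusted p = 0.0533) and for circles of FIRRE (adjusted p = 0.0914), VRK1 (0.0713), CPSF6 (0.0910) and FAT1 (0.0647), all by limma.

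Across the tested circRNAs the median log2 fold change was -0.33, and 40.4% had a higher value in KD. The median was -0.14 without KD replicate 1 and -0.48 without KD replicate 2. It was -0.49 and -0.42 without control replicates 1 and 2. The groups did not overlap for 54.7%. By chance this share is 33.3% only if all 4 libraries vary alike, which the wider spread of the controls contradicts. A shift of whole libraries raises it as well, so the excess was not tested. At an unadjusted p under 0.05, limma gave 124 higher and 340 lower. These counts rest on single libraries and on the scaling. Leaving out control replicate 1 gave 321 higher and 440 lower, without control replicate 2 the counts were 350 and 337, and without KD replicate 1 limma called 0 and 0 (20 and 147 at an unadjusted p under 0.05), and without KD replicate 2 also 0 and 0 (20 and 257). Centring each library on its median turned the split to 3 higher and 1 lower (332 and 129 at an unadjusted p under 0.05) and shifted the median to 0.30; edgeR called 1 and 0, and DESeq2 89 and 201.

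By host gene list, circRNAs of the hosts of much studied circles included 1 that rose (CDR1-AS) and 3 that fell (both MAN1A2 circles among them) of 135 tested; adjusted over the list alone the counts were 3 and 7. No circle passed over all tests in the other 9 lists. Adjusted over the list alone, 1 of 91 circles of kinases and signalling was higher and 4 lower, 1 of 42 from splicing regulators was higher, and 1 each was lower among 69 from centrosome and cilium genes, 40 from nuclear pore and transport genes and 7 from RNA exosome genes and cofactors. Chromatin regulators (140 circles), mRNA decay and translation (55), ubiquitin ligases (85) and zinc finger genes (64) had 0. Of the named members that did not pass, a circle of RANBP2, a nucleoporin (chromosome 2, 108771701 to 108773046), had 1.30 ± 0.242 FPB in controls and 0.193 ± 0.0512 in KD, and one of CEP192, a centriole assembly scaffold (chromosome 18, 12999421 to 13042334), had 3.22 ± 0.217 and 0.740 ± 0.252 (SD, n = 2 each; limma adjusted p = 0.0647 and 0.0616). The known circle in ZKSCAN1 (chromosome 7, 100023419 to 100024307) stood at 2.15 ± 0.216 and 5.36 ± 0.212 FPB (limma adjusted p = 0.0815, n = 2 each). No list as a whole passed camera, where the smallest adjusted p was 0.571 and, with an estimated correlation, 0.887.

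By class, the 809 circRNAs of lowest mean abundance had a median log2 fold change of -0.07 and the 809 of highest abundance one of -0.51. Camera placed the former above and the latter below the other circRNAs (adjusted p = 0.00438 and 0.00270). Neither call held with an estimated correlation (adjusted p = 0.511 for each), with library median centring (0.613 and 0.743) or without control replicate 2 (0.0801 and 0.0712). The 608 circRNAs of lowest and the 608 of highest CIRCscore had medians of -0.68 and -0.54. These classes hold only circRNAs read in all 4 libraries, and set against the others of that kind neither was called (camera adjusted p = 0.894 and 0.711). The 809 circRNAs of shortest genomic span, at a median of -0.20, and the 809 of longest span, at -0.57, were not called (adjusted p = 0.117 and 0.0618).

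To set circles against the linear RNA of their host, CIRCscore was tested for the 1823 circRNAs read in all 4 libraries, which leaves out circles unseen in a control, such as that of TBCD. The deposited fold was above 1 for 33.9% of all tested circRNAs and for 24.4% of all listed ones read in the 4 libraries, so this selection leaves out circles that rose. CIRCscore fell past the threshold for 2 and rose for 0, with 54 higher and 326 lower at an unadjusted p under 0.05 and a median log2 fold change of -0.42. The circle of RHBDD1, a rhomboid protease (chromosome 2, 226864604 to 226867318), went from 2.48 ± 1.63 to 0.0413 ± 8.24e-05, and that of SLC35E2A (chromosome 1, 1734690 to 1739704) from 2.26 ± 0.0941 to 0.120 ± 0.00840 (SD, n = 2 each; limma adjusted p = 0.0483 and 0.0334). In both, the linear RNA rose, from 0.401 to 4.15 FPB and from 0.532 to 4.37. Ratios that were higher in KD without passing included circles of DLEU2 (chromosome 13, 49997074 to 50044768, log2 fold change 3.06) and TJP1 (chromosome 15, 29761139 to 29773357, 2.49). Others were of EXOC6B (chromosome 2, 72718103 to 72733118, 2.55) and SLC16A10 (chromosome 6, 111172695 to 111177665, 2.36). Their limma adjusted p lay between 0.135 and 0.142. The control ratios rested on few backsplice reads: 2 and 3 for DLEU2, 2 and 1 for TJP1, 11 and 6 for EXOC6B, and 1 and 1 for SLC16A10. Without control replicate 1 the counts were 45 higher and 218 lower, without control replicate 2 they were 57 and 228, without KD replicate 1 they were 1 and 7, and without KD replicate 2 they were 3 and 21. With library median centring limma called 0 (157 higher and 129 lower at an unadjusted p under 0.05) and the median was 0.03.

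Linear host RNA was tested once per host gene, in a fit that recovered 99% of simulated 4-fold changes. The FPBcirc fit recovered 0%, in a simulation with noise of another kind. Counts of calls therefore do not compare circles with hosts. Of 2547 host genes, 276 were higher and 607 lower in KD past the threshold, with a median log2 fold change of -0.21. MID1, a microtubule-bound ubiquitin ligase, fell from 3.93 ± 0.0762 to 0.302 ± 0.0325 FPB (SD, n = 2 each; log2 fold change -3.56, SE 0.31, limma adjusted p = 3.08e-27). For most host genes the SE came from a variance shared over genes. A p this small therefore does not measure the spread of a gene between 2 libraries of 1 clone. HMBOX1, a telomere-binding homeobox protein, fell from 4.32 ± 0.415 to 0.0590 ± 0.0493 FPB, and AFF2, a transcription elongation factor, from 1.28 ± 0.271 to 0.108 ± 0.0463 (log2 fold changes -5.64 and -3.23). Abundant ANP32E, the H2A.Z chaperone, fell from 89.7 ± 10.5 to 18.1 ± 6.48 FPB. PIK3R3, POLR3G, ESF1, CCDC18, FASTKD1 and ZBTB46 fell with log2 fold changes between -2.45 and -1.99. Among genes that rose, SAMD4B, an RNA-binding translational repressor, went from 8.07 ± 0.392 to 33.3 ± 5.20 FPB (log2 fold change 2.03) and CASTOR2 from 1.45 ± 0.494 to 6.62 ± 0.378. The transcription factors BCL11B (2.47) and ZNF536 (2.02) and the Golgi protein GASK1A (3.23) rose too. BANP was listed at 0 in both control libraries and at 3.41 and 3.12 FPB in KD, and ARHGAP19-SLIT1 at 6.41 and 8.71 in controls and at 0 in both KD libraries.

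In most lists more host genes fell than rose in linear RNA, as they did among all hosts. Of 71 centrosome and cilium genes, 5 rose and 21 fell, among them CCDC18 (log2 fold change -2.02), CEP162 (-1.57) and CEP290 (-1.22). Of 48 splicing regulators 3 rose and 14 fell, with SNRNP48 (-1.39), HNRNPA2B1 (-1.08), SFPQ (-1.11) and HNRNPM (-1.08) lower. Of 92 kinases and signalling genes 4 rose and 23 fell; FGFR1 (1.55) and HIPK2 (1.40) were higher and VRK1 (-1.67), VRK2 (-1.59) and STK4 (-1.43) lower. Of 111 chromatin regulators 11 rose and 25 fell, including the demethylase KDM4B (1.49) and the deacetylase HDAC2 (-1.56). Nuclear pore and transport genes had 1 riser, TNPO2 (1.24), and 10 that fell, including the exportin XPO1 (-1.25), of 38. mRNA decay and translation had 2 that rose and 11 that fell of 43, with SMG9 at 1.23 and EIF5B at -1.68, and ubiquitin ligases 7 and 14 of 77, with RNF121 at 1.62 and CUL3 at -1.10. In the exosome list, the helicase MTREX (-1.09), ZFC3H1 (-0.86) and HBS1L (-1.47) fell and the poly(A) polymerase TENT4A (1.03) rose, of 8. Zinc finger genes went the other way with 17 up and 8 down of 51, and hosts of much studied circles were split 11 and 10 of 64. Adjusted over the list alone, the counts were the same except 22 lower for centrosome and cilium, 10 higher for hosts of much studied circles, 13 lower for ubiquitin ligases and 10 lower for zinc finger genes. No list passed camera after adjustment; the smallest adjusted p was 0.236, for zinc finger genes (0.991 with an estimated correlation).

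Counts of changed host genes moved with the libraries kept. Without control replicate 1 limma called 77 higher and 223 lower, without control replicate 2 the counts were 128 and 167, without KD replicate 1 they were 268 and 372, and without KD replicate 2 they were 303 and 939. Library median centring gave 554 higher and 593 lower, with a median log2 fold change of -0.03. Uncentred, that median was -0.28 and -0.13 without control replicates 1 and 2. It was -0.06 and -0.36 without KD replicates 1 and 2. All 883 genes called kept their direction in each of these fits. For genes whose groups did not overlap, only centring could have changed it.

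Changes of circles and of their hosts were related. Across 1823 circRNAs the log2 fold changes of FPBcirc and of linear host RNA correlated at r = 0.404 and rho = 0.438 (permutation p = 1e-04 for each, the smallest that the permutations can give; 1 relation was computed, across circRNAs, which are not independent). The hosts of 9 of the called circles that fell, those other than ZDBF2 and MCM3, also had lower linear RNA past the threshold when tested per host gene. VRK1 and ZKSCAN1 are examples among circles that did not pass, with linear log2 fold changes of -1.67 and 1.16 and circle log2 fold changes of -1.29 and 1.31. Others differed in sign from their host: circles of ZNF236, TENT4A and FAT1 had log2 fold changes of -1.56, -0.76 and -1.74, with linear RNA at 1.24, 1.03 and 0.33. These circles did not pass either (limma adjusted p = 0.132, 0.273 and 0.0647). The linear rise passed for ZNF236 and TENT4A but not for FAT1 (limma adjusted p = 0.339).

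**Figure D3:**
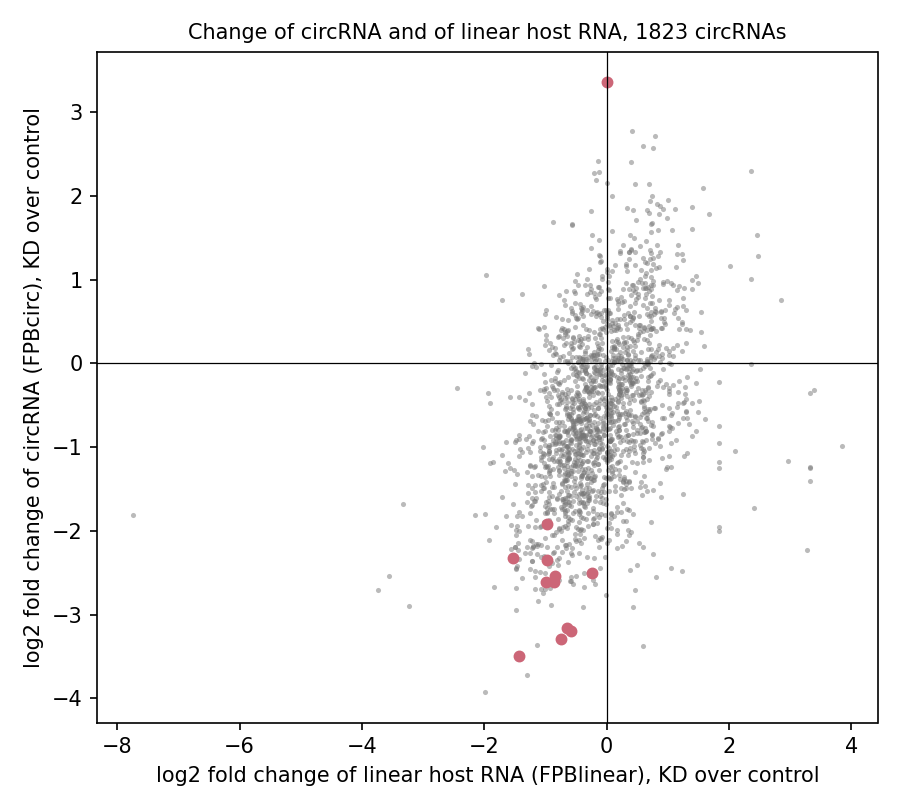
log2 fold change (KD over control) of each circRNA's FPBcirc against that of the linear RNA of its host gene, for 1823 circRNAs with a value in all 4 libraries; red points passed the threshold for FPBcirc. The cloud slopes upwards with r = 0.404.

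The change of linear host RNA differed between chromosomes, around the median of -0.21 for all host genes; those named here were chosen after their values were seen. Host genes on chromosome 2 had a median log2 fold change of -0.58, with 101 of 221 lower and 8 higher past the threshold. Those on chromosomes 5 and 6 had medians of -0.63 and -0.64, and on chromosome 1 of -0.42. Host genes on chromosome 19 had a median of 0.68, with 37 of 74 higher and 4 lower, and those on chromosome 16 a median of 0.19. Median FPBcirc changes were -0.69 on chromosome 2, -0.89 on 5, -0.80 on 6 and 0.63 on 19. On other chromosomes circles and hosts differed, with hosts at 0.15 and circles at -0.40 on chromosome 18, 0.13 and -0.45 on 22, -0.26 and -0.85 on 13, and -0.18 and 0.01 on 15.

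**Figure D4:**
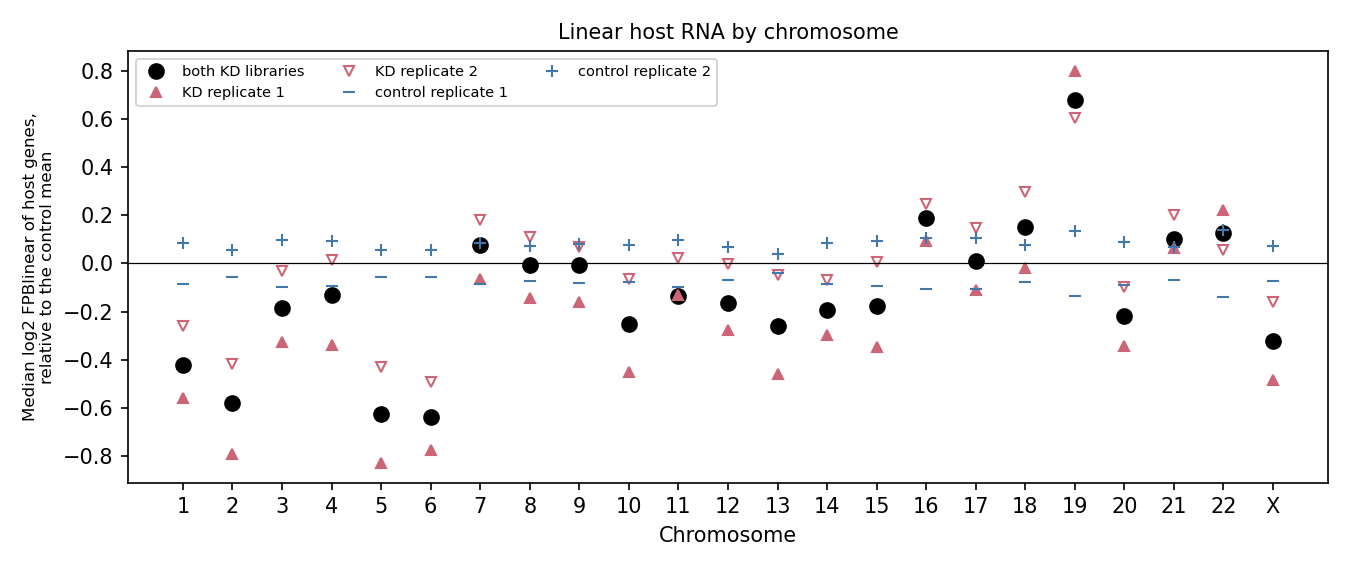
Median log2 FPBlinear of host genes per chromosome relative to the control mean, for both KD libraries together (black) and for each library. Both KD libraries lie below the controls on chromosomes 1, 2, 5 and 6 and, by smaller margins, on 13, 20 and X. They lie above both controls on chromosome 19.

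In the authors' deposited table, 75.1% of the 45182 listed circRNAs had a fold above 1. Among the 2427 tested circRNAs that share was 33.9%. Of 1207 circRNAs with a deposited fold of 2 or more, 900 had no control read, and 2092 had a fold of 0.5 or less. The deposited fold of CDR1-AS was 9.96 and that of the TBCD circle 18.9. The log2 deposited fold correlated with the fitted log2 fold change at r = 0.961 and rho = 0.956 across the tested circRNAs, and 92.5% had the same sign.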

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

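The tests with TMM, thinned reads, 1 linear value per host gene, genomic span, circRNAs with linear reads in all libraries, CIRCscore classes among circRNAs read in all 4 libraries, and without CDR1-AS were chosen after the data were seen. All 13 circRNAs called for FPBcirc kept their sign in every alternative. Their groups did not overlap, so only another scaling or thinning could have turned it. The number called did not keep its size, and the cause was not tested unless given. With FPBcirc the counts higher and lower were 20 and 30 at 5 times the pseudocount, 48 and 61 without a filter, 27 and 111 at the stricter filter, 3 and 1 with library median centring, 0 and 0 in limma without trend and robust moderation (135 and 301 at an unadjusted p under 0.05), 1 and 0 in edgeR with mapped bases or with TMM (unadjusted 136 and 340, and 287 and 148), 89 and 201 in DESeq2, and 7 and 19 with KD reads thinned. Leaving out 1 library gave 0 to 350 higher and 0 to 440 lower; the lone library was assumed to vary like the other pair, so leaving out a control replaces the wide control spread (coefficient of variation beyond counting 0.778) by the narrow KD spread (0.356). The median log2 fold change of FPBcirc turned to 0.30 without a filter, 0.30 with centring and 0.10 with TMM.

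For CIRCscore, leaving out 1 library gave 1 to 57 higher and 7 to 228 lower; the lower count was 1 at 5 times the pseudocount, 0 with centring and 0 without trend and robust moderation (58 and 327 unadjusted), and the stricter filter gave 5 and 54. Its median turned to 0.0325 with centring. Linear RNA per circRNA gave 62 to 240 higher and 119 to 639 lower with 1 library left out; per host gene it gave 77 and 223 without control replicate 1, 128 and 167 without control replicate 2, and up to 303 and 939 without KD replicate 2, and 554 higher with centring. The log2 ratio of total circRNA moved from -0.16 to -0.37 for tested circRNAs and -0.50 for those in all 4 libraries, and stayed below 0 throughout. It was close to 0 without KD replicate 1, as KD replicate 2 summed to 2536 FPB against a control mean of 2600. Neither subset is neutral. The filter can favour circRNAs high in a control, and the choice of circRNAs read in all 4 libraries leaves out circles that rose. The sign in these subsets therefore does not show a general fall. Of the 4 classes called against all other tested circRNAs, 2 were CIRCscore classes, which hold only circRNAs read in all 4 libraries; set against such circRNAs alone, these were not called and 2 classes were left. Of the 4, 0 were called with an estimated correlation, 0 with fry, 1 with centring and 2 without control replicate 2, all of them CIRCscore classes. No host gene list was called in a directional test under any setting. The mixed test of fry, which takes changes in either direction together, called 9 of 10 lists for FPBcirc (adjusted p from 0.00658 to 0.0312) and 0 for linear RNA. It also called all 6 circRNA classes, so it does not single out the lists.

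Replicate numbers showed little pairing across features: deviations of libraries with the same number correlated at 0.00289 for FPBcirc, 0.0271 for CIRCscore and 0.0832 for linear RNA. This check cannot see a shift of a whole library. Replicate 1 lay below replicate 2 in summed FPBcirc in controls (2500 and 2700) and in KD (2130 and 2536). Median linear host RNA did so too (7.76 and 8.66, and 6.60 and 7.94 FPB). A pairing by replicate number is thus not excluded. With the replicate block the counts were 36 higher and 98 lower for FPBcirc, 1 and 8 for CIRCscore, and 374 and 784 for linear RNA per host gene.

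Classes by exon number, spliced length, circRNA type and base content, planned before the data were examined, were not run, as no genome was used here. Depth limits the controls most, where 1 read is worth 0.0511 and 0.0489 FPB.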

Other observations

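The tests of shared circRNAs, of the slope between circles and hosts, of their relation within chromosomes, of circles that moved apart and of the chromosome as the unit were chosen after the data were seen; those of chromosomes by GC content, of thinned folds and of the sign of circles within a host were written before their result. Of these, 4 took the place of tests already run that were void or did not measure what had been written: the correlation of linear RNA in each pair of libraries (difference -0.000236), the correlation of circles with hosts (0.404), chromosome 2 against 3 and 4 (-0.41), and pairs of 1 host on the same side of the median (59.95%). Chromosome 2 was singled out because its host genes were low. They were lower along most of its length: 23 of 25 bins of 10 Mb had a median below that of all host genes. The same held for 17 of 18 bins on chromosome 6, 19 of 24 on 1 and 14 of 19 on 5, and for 0 of 6 on 19. The median against the control mean was -0.80 in KD replicate 1 and -0.42 in KD replicate 2, while chromosome 4 stood at -0.34 and 0.02. FPBcirc was lower on chromosome 2 than on chromosomes 3 and 4 by a median of -0.33, whereas CIRCscore differed by 0.05.

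A hypothesis was that a change is shared by all circles of a host: log2 fold changes of pairs from 1 host had the same sign in 60.80% of cases, averaged over hosts, against 52.6% after shuffling (permutation p = 5e-04, the smallest that the shuffles can give). This shows a tendency of pairs, not a change of all circles, and a like test had already been run on the same values. Circles that moved apart were rarer than by chance: in 28 of 497 hosts with several tested circRNAs, 1 circle was higher and another lower by more than 1 on the log2 scale with groups that did not overlap, against a mean of 68.1 hosts after shuffling (48 to 90). In 0 of the 28 had both circles passed the threshold.

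The control libraries shared few circRNAs with each other. With KD reads thinned to control depth, 45.9% of circRNAs with 5 or more reads in a control library had 0 in the other, against 10.5% in the KD pair, a ratio of 4.39, which argues against lower depth of the controls as the whole cause. For 1499 of the 1943 circRNAs with 5 or more reads in 1 control and 0 in the other, linear host RNA was known in both, and its median log2 difference was 0.0375 (percentiles 10 and 90, -0.30 and 0.37). This argues against a difference in host gene expression for these; the rest, and a difference between the cultures in their circRNAs, stay open. What also stays open is that the control libraries may hold fewer circRNA molecules, each read several times: circRNAs with 1 read were rarer relative to those with 2 (1.29 against 2.75, a ratio of 0.469). Library handling and group are confounded here, and an effect of DIS3 depletion on the number of different circles was not tested apart from it.

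That circles fell and rose with their hosts has 3 candidate explanations. If circles followed their linear host RNA in full, the slope between the changes would be 1. It was 0.53 (95% bootstrap interval 0.43 to 0.64), which argues against following in full. Error in the host changes and the pseudocount can lower this slope, and neither was corrected for. Following in part stays open. Host genes on chromosomes rich in GC (16, 17, 19, 20 and 22) were higher than those on GC-poor ones (3, 4, 5, 6, 13 and 18) by a median of 0.48 (exact permutation p = 0.0173 over the 462 ways to split the 11 chromosomes), as a base composition difference between libraries could produce. Single chromosomes did not all go that way: GC-poor 18 stood at 0.15, GC-rich 20 at -0.22, and without chromosomes 5, 6 and 19 the difference was 0.17. A different number of copies of whole chromosomes in the KD clone is argued against as the whole cause: with the median of each chromosome taken from both changes, they still correlated at r = 0.359 (95% bootstrap interval 0.309 to 0.410). Whether it lies behind the differences between chromosomes was not tested. With 1 clone and no DNA data this and an effect of DIS3 itself stay open.

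The 75.1% of deposited folds above 1, among 45182 circRNAs, may come from the deeper sequencing of the KD libraries: with KD reads thinned, the share was 58.9% of the 28001 circRNAs left on average over 20 draws (36.5% of those listed). Among those left, an excess over folds below 1 (37.7%) remained.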
